A study of Homo sapiens with 11 samples.

How the data were processed

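The values analysed were read counts per gene, deposited by the authors as 1 table with 1 column for each of the 11 libraries: 1 parental, 5 persister and 5 withdrawn. Per the labels' protocols, RNA was extracted with a column kit and made into stranded poly(A) libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, aligned with HISAT2 to hg38 and counted with HTSeq. Versions, the strand setting of the counting and the annotation release are not given in the sources used here. The deposited counts are whole numbers, not normalized, and replicates were not pooled. Poly(A) selection leaves RNA without a poly(A) tail at low levels that can vary with the selection. Because strand use is not stated, reads of genes that overlap on opposite strands may be mixed: 46 of 128 named genes share exon bases with another gene, 40 of them with a gene on the opposite strand. Sizeable overlaps include BRAF with NDUFB2, CCNE2 with INTS8 and MAP2K1 with SNAPC5. Counts of IFITM2, IFITM3, FCGR2A, NBPF1, ribosomal protein and mitochondrial genes are uncertain to the extent that reads are shared with close copies.

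All 58721 gene IDs of the table matched GENCODE release 29, from which symbols and GRCh38 coordinates (1-based) were taken, and 18024 genes had 0 counts in all libraries. Total counts ranged from 56513920 to 82984566 per library. At this depth a gene with 0 counts in a group was set against a floor of 3 counts over the group, and the counts of the other group were pooled and divided by its pooled library size. For genes with 1 to 3 counts the ratio is given with its 95% counting interval, and such intervals and floors cover counting error only.

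Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with the 3 groups (minimum count 10, minimum total 15), TMM scaling, robust quasi-likelihood fits of all 11 libraries with 3 groups, and Benjamini-Hochberg adjustment over the 23693 genes tested, with a threshold of 0.05. The fit has 8 residual degrees of freedom, which come from the persister and withdrawn libraries. CPM values and log2 fold changes were computed from the deposited counts with these scaling factors, and correlations used log2 CPM with a prior count of 2. Genes were classed by their calls. Reverted genes were called between persister and parental cells, called in the opposite direction after withdrawal and not called between withdrawn and parental cells. Retained genes were called in the same direction against parental cells in both and not called after withdrawal. Partly reverted genes were called in all 3 comparisons with the same direction against parental cells, and overshot genes were called in opposite directions against parental cells.

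The 29 gene lists were written from general knowledge of melanoma, MAPK inhibition and drug tolerance, with markers of other cell types and signs of RNA quality among them. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 87 tests of lists and comparisons, and also with an estimated correlation and with fry, which tests whether the genes of a list move, on balance, one way. The comparisons, the tests of genes and lists, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. Those chosen later are named as such. Named genes were the 8 largest rises and 8 largest falls of each comparison, among genes past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups. They further include the 3 members with the smallest adjusted p of each list that passed, 15 genes of interest, and up to 5 genes of each class. Non-coding, pseudogene and Y-linked names were left out of the ranking, and some genes that the rule names are not reported here. The rule gave more genes per comparison than intended because many lists passed.

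The tests were tried on simulated counts with known changes, drawn from the real means and library sizes, with 66 or 67 genes changed at each fold. Simulated persister counts had the spread of the persister libraries, and parental and withdrawn counts that of the withdrawn libraries. In the comparison of withdrawn with persister cells, edgeR recovered 17.9% of 1.5-fold, 65.7% of 2-fold and 87.9% of 4-fold changes among 22477 genes, with 13 false calls of 127. For persister against parental cells it recovered 14.9% of 2-fold and 63.6% of 4-fold changes among 22512 genes, with 1 false call of 53. For withdrawn against parental cells it recovered 5.97% and 78.8% among 22530 genes, with 0 false calls of 56. The false calls against parental cells do not cover a parental library that varies more than the withdrawn libraries.

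Withdrawn samples are named after the persister culture of the same number, which pairs them. Deviations from the group means of same-numbered libraries had correlations of 0.0484, 0.0587, 0.0735, 0.0737 and 0.0909 across genes, the highest for the own number in 5 of 5 pairs (exact permutation test over 120 pairings, one-sided p = 0.00833). Replicates of a group differed by more than sampling noise, so none was counted as a duplicate. Alternatives were other scaling factors, other low-count filters, DESeq2 1.42.0, limma-voom, a fold threshold, the replicate block, smaller sets of libraries and leaving out each library in turn. Chosen after seeing the data were fits of each comparison on its own libraries, voom with group quality weights and leaving out mitochondrially encoded genes. A further alternative that left out persister 1 and 5 was set up and dropped before its values were read, because it chose libraries by a measured outcome.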

Results

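Poly(A) RNA was sequenced from A375, an established human melanoma cell line that carries an activating BRAF mutation. Of the 11 libraries, 1 came from untreated parental cells, 5 from persister cells that had been kept in 2 nM trametinib for 8 weeks, and 5 from cells taken 4 weeks after the drug was withdrawn (withdrawn cells). Trametinib inhibits the MEK kinases, which act downstream of BRAF. Each withdrawn sample is named after the persister culture of the same number. Total counts ranged from 56513920 to 82984566 per library and 23693 genes were tested. Nothing in the labels says whether the 5 persister cultures were selected separately, so p-values measure only the spread between these samples, which may be technical. The parental group holds 1 library, so it has no spread of its own and was taken to vary like the other libraries. Values are CPM, counts scaled to an equal library size, as mean ± SD over n = 5 for the persister and withdrawn groups. Unless another test is named, p-values are from edgeR's quasi-likelihood test for genes and from camera, with a preset correlation, for gene lists, both adjusted by the Benjamini-Hochberg method.

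Persister cells were compared with parental cells to see what differed in the cells that had lived through the drug. DUSP6, a phosphatase of ERK, fell 6.76-fold from 168 to 24.8 ± 4.78 CPM (log2 fold change -2.76 ± 0.17 (SE), adjusted p = 1.31e-06). SPRY4 fell 25.9-fold from 445 to 17.2 ± 7.95 CPM (adjusted p = 1.55e-05), and SPRY2 fell 6.52-fold. SOX10, a transcription factor of the neural crest and melanocyte lineage, fell 12.2-fold from 635 to 51.9 ± 23.9 CPM (log2 fold change -3.61 ± 0.36 (SE), adjusted p = 5.78e-05). CDKN1A, which encodes the cell cycle inhibitor p21, rose 8.44-fold from 60.6 to 512 ± 76.4 CPM (log2 fold change 3.08 ± 0.26 (SE), adjusted p = 1.25e-05). The DUSP6, SOX10 and CDKN1A genes lie on chromosomes 12 (89347232 to 89353271), 22 (37970686 to 37987422) and 6 (36676460 to 36687339) of GRCh38.

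The largest rises were in genes that parental cells barely transcribed. MME, which encodes the membrane peptidase neprilysin, stood at 0.168 CPM in parental and 2234 ± 988 CPM in persister cells (adjusted p = 0.00186). TRPC4, ROS1, RARRES2, CNTN6, SPINK6 and CHRM2 had 0 counts in the parental library. Set against a floor of 3 counts in that library, their counts, pooled over the 5 persister libraries and set to the pooled library size, were higher by at least 3516-fold, 1336-fold, 1026-fold, 921-fold, 777-fold and 717-fold. Each of the 6 lost its call with limma-voom, with adjusted p from 0.0680 for CNTN6 to 0.398 for ROS1. TRPC4 also lost it without a low-count filter and with voom and group quality weights (over all alternatives up to 0.243), and ROS1 with those weights and in fits of 6 libraries. The persister cultures differed widely in some of these genes: ROS1, a receptor tyrosine kinase, averaged 56.7 ± 47.4 CPM and SPINK6 33.8 ± 39.6 CPM. SPINK6 stood at 104 CPM in persister 5 and at 9.94 to 22.5 in the other persister libraries, and its log2 fold change was 14.15 with persister 5 and 13.08 without it. POSTN, a matrix protein, had 1 count in parental cells and averaged 757 ± 1368 CPM in persister cells, a ratio of 57986 (95% counting interval 10407 to 2290340.0). Persister 4 carries this mean, at 3203 CPM against 75.6 to 225 in the others, and without it the log2 fold change was 13.05 instead of 15.43. Its call (adjusted p = 0.0473) ended without persister 3 or without withdrawn 1, 3 or 4, with adjusted p reaching 0.0630, and its adjusted p ranged from 0.0204 to 0.437 over all alternatives. The largest falls were in SLC24A2, ART3, LAD1, MUC5B, CHRDL1, CEMIP, ANO1 and SHISA2. SLC24A2, a cation exchanger, went from 21.4 to 0.0113 ± 0.0179 CPM, ART3 from 34.5 to 0.0248 ± 0.0312 CPM and LAD1 from 14.6 to 0.0153 ± 0.0165 CPM. CEMIP, a hyaluronan-binding protein, fell from 457 to 1.57 ± 1.27 CPM, CHRDL1 from 82.99 to 0.248 ± 0.194 CPM, MUC5B from 31.7 to 0.0498 ± 0.0502 CPM, ANO1 from 32.6 to 0.118 ± 0.0712 CPM and SHISA2 from 51.1 to 0.225 ± 0.101 CPM. The log2 fold change of SLC24A2 was -10.62, and -11.90 without persister 5, and that of ART3 -10.41, and -11.10 without persister 2.

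Of the 29 gene lists fixed beforehand, 15 passed the test in this comparison. Over all 23693 genes tested, 3819 were higher and 3572 lower, together 31.2%. In the list of MAPK pathway output, 19 of 30 genes fell and 1 rose (adjusted p = 5.59e-12, and 0.307 with an estimated correlation). In the neural crest-like list 10 of 25 fell and 2 rose (adjusted p = 1.63e-04, and 0.654 with an estimated correlation). RXRG, a retinoid receptor, fell 26.3-fold and SOX2 5.595-fold, whereas GFRA1, a receptor of the GDNF ligand family, rose 365-fold from 0.184 to 67.7 ± 21.96 CPM. In the pigmentation list 9 of 21 rose and 1 fell (adjusted p = 0.00815, and 0.654 with an estimated correlation). MLANA, a melanosome protein, rose 13.96-fold and the transcription factor TFAP2A 3.66-fold. OCA2, a melanosome membrane protein, had 0 counts in all persister libraries and was, from pooled counts, at least 233-fold lower than in parental cells, with the floor of 3 counts taken over the group. Adjusted over the list alone, the numbers that rose and fell were 1 and 20 for MAPK output, 2 and 11 for neural crest-like, 10 and 1 for pigmentation.

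Lists of the undifferentiated state and of the extracellular matrix rose. In the undifferentiated AXL-high list 12 of 25 genes rose and 0 fell (adjusted p = 0.00359, and 0.654 with an estimated correlation), among them the lysyl oxidase LOXL2 (3.55-fold), the kinase NUAK1 (5.56-fold) and the matrix protein TGFBI (5.25-fold, 166 to 872 ± 261 CPM). In the mesenchymal and matrix list 15 of 34 rose and 4 fell (adjusted p = 0.00374, and 0.654 with an estimated correlation): the metalloprotease MMP2 rose 7.86-fold and COL5A2 3.57-fold, while COL6A3 fell 8.67-fold. In the TGF-beta list 12 of 23 rose and 1 fell (adjusted p = 0.0145, and 0.654 with an estimated correlation). BMP1 rose 3.61-fold, and INHBA, the activin subunit, fell 3.47-fold. Among the fibroblast markers 6 of 11 rose and 1 fell (adjusted p = 0.0192, and 0.654 with an estimated correlation). LUM rose 79.7-fold to 172 ± 111 CPM and FAP 30.3-fold. COL1A2, an abundant fibroblast transcript, had 3 counts in parental cells and reached 1.32 ± 0.756 CPM in persister cells, a ratio of 27.3 (95% counting interval 9.29 to 133). With fry the AXL-high list did not pass (adjusted p = 0.0569). Adjusted over the list alone, the numbers that rose and fell were 13 and 0 for the AXL-high list, 16 and 6 for the matrix list, 12 and 1 for TGF-beta, 6 and 1 for fibroblast markers.

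Lists of growth arrest, immunity and metabolism also moved. In the list of p53 targets and cell cycle inhibitors 14 of 25 rose and 1 fell (adjusted p = 2.56e-05, and 0.307 with an estimated correlation), with BTG2 4.47-fold and SESN2 2.72-fold higher. In the S phase list 3 of 39 fell and 0 rose (adjusted p = 0.00222, and 0.780 with an estimated correlation): E2F2 by 4.44-fold and the DNA polymerase genes POLA1 and POLE by 2.82-fold and 2.63-fold. The share of S phase genes that fell is below that over all genes. The mean log2 CPM of the S phase list was 6.02 in parental cells, 4.58 in persister 1 and 3.58 in persister 5, and it lay between 5.39 and 5.79 in the other persister libraries. In the interferon list 22 of 41 rose and 1 fell (adjusted p = 7.08e-05, and 0.654 with an estimated correlation), including ISG15 (16.5-fold), IFITM2 (4.61-fold) and IRF1 (3.58-fold). In the antigen presentation list 15 of 25 rose and 7 fell (adjusted p = 0.0112, and 0.717 with an estimated correlation). The immunoproteasome genes PSMB9 and PSMB8 rose 3.86-fold and 3.29-fold. In the lysosome list 26 of 33 rose and 1 fell (adjusted p = 9.42e-09, and 0.654 with an estimated correlation), with GABARAPL1 4.88-fold, LAMP1 2.53-fold and LAMP2 2.53-fold higher. In the list of nuclear genes of oxidative phosphorylation 25 of 37 rose and 1 fell (adjusted p = 3.61e-06, and 0.654 with an estimated correlation): ATP5MC1 rose 2.602-fold, COX7C 2.39-fold and UQCRB 2.37-fold. Of the mitochondrially encoded genes 7 of 13 rose and 0 fell (adjusted p = 0.00127, and 0.654 with an estimated correlation), including MT-CO2 (3.78-fold), MT-ND1 (3.08-fold) and MT-CYB (2.69-fold). Mitochondrial genes took 2.96% of counts in the parental library and 6.81% ± 2.26 in the persister libraries. They took 3.55% ± 0.226 in the withdrawn libraries (exact two-sided permutation test of persister against withdrawn, p = 0.00794, the smallest 5 against 5 can give). That permutation test ignores the pairs of same-numbered libraries. Of the cytosolic ribosomal protein genes 4 of 40 rose and 0 fell (adjusted p = 0.0314, and 0.816 with an estimated correlation), RPS20 by 1.54-fold, RPL13 by 1.47-fold and RPL37 by 1.399-fold. The share that rose is below that over all genes. The call of the ribosomal list ended without persister 1 (adjusted p = 0.0817) or persister 3 (0.0582), within a range of 1.55e-04 to 0.816 over all alternatives. RPL37 alone lost its call without persister 3 or without any 1 of the withdrawn libraries, with adjusted p of up to 0.0587 there and from 0.00113 to 0.195 over all alternatives. With fry the lists of S phase (adjusted p = 0.171), interferon (0.0700), antigen presentation (0.0595), mitochondrially encoded (0.0595) and ribosomal protein genes (0.171) did not pass. Adjusted over the list alone, the numbers that rose and fell were 16 and 1 for p53 targets, 0 and 3 for S phase, 26 and 1 for interferon, 16 and 7 for antigen presentation, 27 and 1 for lysosome. They were 30 and 1 for oxidative phosphorylation, 10 and 0 for mitochondrially encoded genes, 0 and 0 for ribosomal proteins. The lists that did not pass are given with the numbers higher and lower, and in brackets those adjusted over the list alone and the list's adjusted p. They were 0 and 0 of 35 for mitosis (0 and 0, 0.111), 6 and 9 of 33 for the Mediator complex (7 and 10, 0.284), 2 and 9 of 24 for cholesterol synthesis (2 and 10, 0.0633), 4 and 1 of 13 for keratinocyte markers (5 and 1, 0.0878), 11 and 5 of 30 for YAP and TEAD targets (14 and 5, 0.439). There were 11 and 5 of 36 for receptor tyrosine kinases (11 and 8, 0.525), 9 and 3 of 29 for NF-kB and inflammatory secretion (9 and 3, 0.443), 7 and 1 of 16 for the AP-1 family (7 and 1, 0.216), 0 and 7 of 24 for glycolysis (0 and 7, 0.0877), 6 and 1 of 30 for stress and unfolded protein response (6 and 1, 0.422). There were 9 and 6 of 24 for drug tolerance markers (10 and 7, 0.473), 1 and 3 of 9 for leukocyte markers (1 and 3, 0.214), 2 and 3 of 10 for endothelial markers (2 and 3, 0.383), 3 and 0 of 18 for heat shock (3 and 0, 0.741). The median and the test differed in sign for glycolysis, leukocyte markers and heat shock. With fry 6 of these lists passed: Mediator (adjusted p = 0.0326), glycolysis (0.00677), cholesterol synthesis (0.00520), leukocyte (0.00221) and endothelial markers (0.0323) were lower and keratinocyte markers (0.00836) higher. The mitosis list passed, lower, without a low-count filter (0.0274), with limma-voom (0.0446), with the 6 persister and parental libraries (0.0437) and without persister 2 (0.0477) or 3 (0.0425). It also passed with voom and group quality weights (8.29e-04), a choice made after seeing the data. Cholesterol synthesis also passed with DESeq2 (0.0421), without a low-count filter (0.0300) and without persister 2 (0.0434), keratinocyte markers without that filter (0.0179) and leukocyte markers with at least 10 counts in 5 libraries (0.0310).

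Several genes of interest did not pass the test between persister and parental cells. MITF, the melanocyte lineage factor, stood at 78.4 and 102 ± 12.9 CPM (adjusted p = 0.219), and AXL, a receptor tyrosine kinase, at 210.3 and 279.9 ± 145 CPM (0.605). NGFR stood at 42.6 and 41.8 ± 28.8 CPM (0.981), EGFR at 13.9 and 27.6 ± 11.8 CPM (0.153), CCND1 at 399.8 and 218 ± 119 CPM (0.171) and BRAF at 53.7 and 46.98 ± 5.41 CPM (0.323). The proliferation marker MKI67 stood at 865 and 384 ± 275 CPM (0.322). Some genes of interest passed under an alternative: CCND1 without persister 2 (adjusted p = 0.00216), CDK19 without persister 5 (0.0232), and both, with EGFR (0.0483) and MKI67 (0.0483), with voom and group quality weights, a choice made after seeing the data. The series concerns the Mediator complex, which couples transcription factors to RNA polymerase. Of 33 Mediator genes 6 rose and 9 fell, and the list did not pass the test (adjusted p = 0.284), while with fry it passed as lower (0.0326). MED12, CDK8 and CCNC, parts of its kinase module, fell 2.02-fold, 1.66-fold and 1.43-fold. CDK19 stood at 30.1 and 22.6 ± 3.22 CPM (adjusted p = 0.0880), and MAP2K1, which encodes MEK1, fell 1.304-fold. In all, 3819 genes were higher and 3572 lower in persister than in parental cells. With limma-voom the balance turned, to 3059 higher and 3915 lower, and with DESeq2 it was 4654 and 3843. With the 6 persister and parental libraries alone, 1354 were higher and 1215 lower, and CDK8 (adjusted p = 0.0545), CCNC (0.124), MAP2K1 (0.191), ROS1, POSTN, COL1A2, POLA1, POLE, MT-CO2, MT-CYB, RPS20, RPL13 and RPL37 lost their calls. Their folds differed little: the log2 fold changes of CDK8, POLE and MT-CO2 were -0.73, -1.39 and 1.92 in that fit and -0.73, -1.40 and 1.92 with all libraries. Of simulated changes, that fit recovered 0% of 2-fold and 4.55% of 4-fold ones, with 2 false calls of 5. The simulation changed only 66 or 67 genes at each fold, whereas that fit called far more in the real data. Recovery in the real data may therefore differ, and the simulation cannot decide what a lost call there means.

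Withdrawn cells were compared with persister cells to see what changed once the drug was gone. DUSP6 rose 7.52-fold to 186 ± 9.28 CPM (log2 fold change 2.91 ± 0.12 (SE), adjusted p = 2.81e-08), SPRY4 25.7-fold to 442 ± 60.7 CPM and SPRY2 6.65-fold. ETV5, an ERK-induced transcription factor, rose 3.07-fold. SOX10 rose 15.7-fold to 814 ± 20.02 CPM (log2 fold change 3.97 ± 0.29 (SE), adjusted p = 1.24e-06), and RXRG 39.2-fold. CDKN1A fell 6.64-fold to 77.1 ± 9.17 CPM (log2 fold change -2.73 ± 0.13 (SE), adjusted p = 5.17e-08). Each of these was seen in all 5 withdrawn against all 5 persister libraries without overlap.

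SLC24A2, ART3, LAD1, CHRDL1, CEMIP and MUC5B, which had been nearly silent in persister cells, stood at 21.5 ± 3.25, 36.5 ± 6.00, 14.7 ± 1.35, 107 ± 22.3, 643 ± 93.2 and 11.2 ± 1.86 CPM. For MUC5B this is below the 31.7 CPM of parental cells. ITIH5 rose from 0.305 ± 0.258 to 169.8 ± 70.5 CPM and the integrin gene ITGA9 from 0.323 ± 0.2697 to 81.9 ± 8.85 CPM. The largest falls were in SPINK6, CHRM2, GUCY1A2, OLR1, MYOCD, DIO2, ROS1 and ACKR3. OLR1, a scavenger receptor, fell from 33.05 ± 14.5 to 0.0264 ± 0.0287 CPM and DIO2, a deiodinase, from 113 ± 53.6 to 0.191 ± 0.187 CPM. SPINK6 fell to 0.0118 ± 0.0182, CHRM2 to 0.0242 ± 0.02995 and ROS1 to 0.101 ± 0.0612 CPM. GUCY1A2 went from 28.1 ± 29.8 to 0.0207 ± 0.0294 CPM, MYOCD from 49.5 ± 71.7 to 0.0772 ± 0.156 CPM and ACKR3 from 22.01 ± 13.8 to 0.0561 ± 0.0668 CPM. Leaving out 1 library moved some of these folds by more than 1.5 times, given here as log2 fold changes with the value from all libraries in brackets. Without persister 2 ART3 was at 11.18 (10.49), and without persister 4 ITIH5 was at 9.67 (9.04), ITGA9 at 8.60 (7.92), GUCY1A2 at -9.37 (-10.27) and MYOCD at -8.00 (-9.24). Without persister 5 SLC24A2 was at 11.90 (10.63) and SPINK6 at -10.20 (-11.26). Without withdrawn 1 OLR1 was at -10.95 (-10.17), and without withdrawn 3 ACKR3 was at -9.28 (-8.56) and DIO2 at -9.79 (-9.17). Without withdrawn 4 MYOCD was at -12.36, GUCY1A2 at -11.54 and CHRM2 at -11.32 (-10.36), and without withdrawn 5 SPINK6 was at -12.53. MYOCD lost its call with limma-voom (adjusted p = 0.181).

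**Figure D1:**
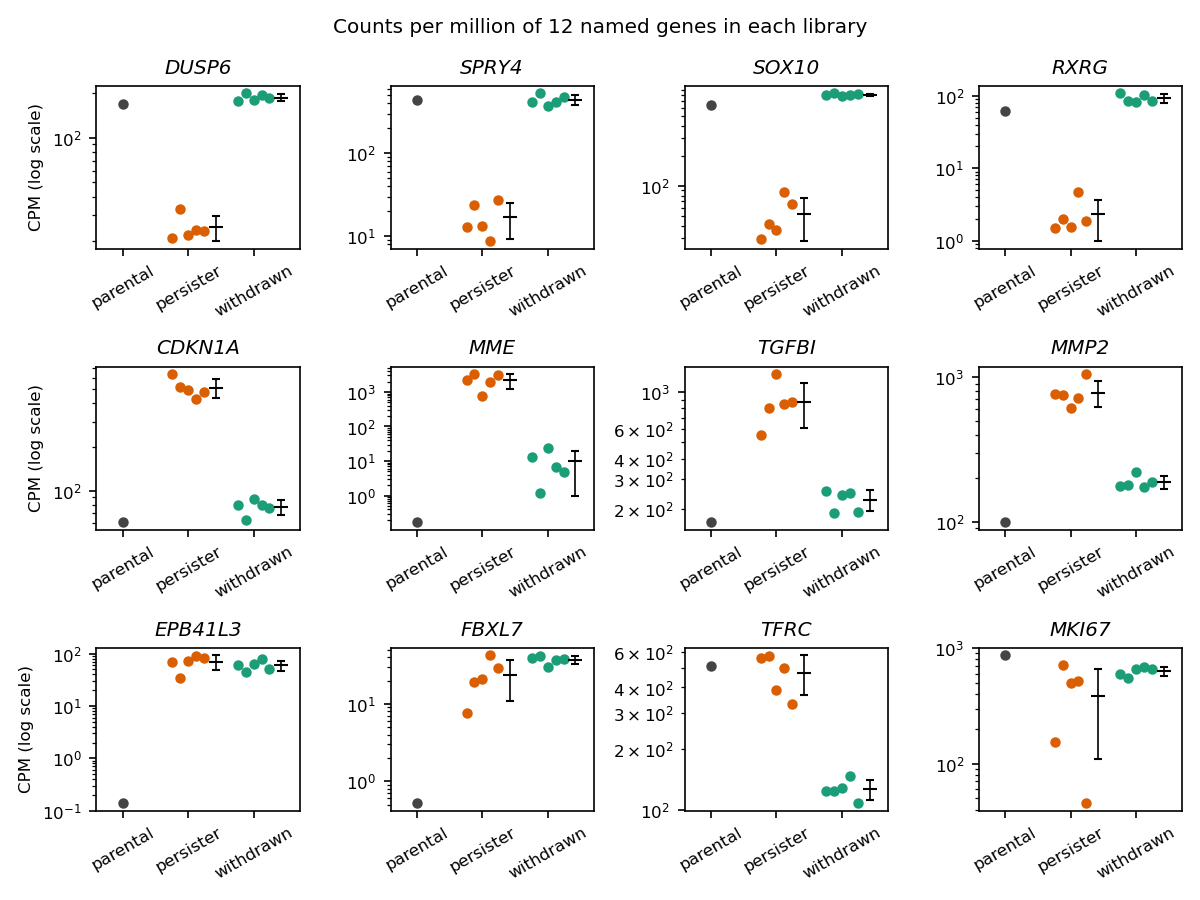
CPM on a log axis for 12 named genes in each of the 11 libraries. Points are libraries (1 parental, 5 persister, 5 withdrawn), and the bar beside each group of 5 gives its mean and SD; DUSP6 lies at 168 CPM in parental cells, at 24.8 ± 4.78 in persister and at 186 ± 9.28 in withdrawn cells, while EPB41L3 stays high after withdrawal at 59.4 ± 12.8.

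Of the 29 lists, 14 passed the test after withdrawal. Over all 23693 genes tested, 5794 were higher and 6634 lower, together 52.5%. In the MAPK pathway list 22 of 30 rose and 4 fell (adjusted p = 1.56e-10, and 0.321 with an estimated correlation), and in the neural crest-like list 15 of 25 rose and 2 fell (adjusted p = 7.08e-05, and 0.628 with an estimated correlation). GFRA1 fell 13.6-fold. The undifferentiated AXL-high list had 15 of 25 lower and 2 higher (adjusted p = 6.20e-04, and 0.654 with an estimated correlation): SLC22A4 fell 3.88-fold, LOXL2 2.85-fold and TGFBI 3.87-fold. The mesenchymal and matrix list had 20 of 34 lower and 6 higher (adjusted p = 0.00864, and 0.654 with an estimated correlation): COL5A1 fell 35.1-fold, THBS1 13.4-fold from 4168 ± 1419.9 to 311 ± 77.1 CPM and MMP2 4.16-fold. In the TGF-beta list 13 of 23 fell and 4 rose (adjusted p = 0.0188, and 0.654 with an estimated correlation), with BMP1 2.97-fold lower and INHBA 7.598-fold higher. Among fibroblast markers 7 of 11 fell and 1 rose (adjusted p = 0.0409, and 0.654 with an estimated correlation): LUM fell 42.2-fold, DCN 28.2-fold and THY1 16.8-fold. That list lost its call without persister 2 (adjusted p = 0.0623) or persister 5 (0.131), within a range of 1.18e-04 to 0.654 over all alternatives. Among keratinocyte and epithelial markers 7 of 13 fell and 1 rose (adjusted p = 0.0303, and 0.654 with an estimated correlation): PERP fell 2.66-fold, KRT10 1.52-fold, and IVL, at 0 counts in all withdrawn libraries, was at least 83.9-fold lower. It lost its call without persister 1 (adjusted p = 0.0596, over a range of 3.16e-04 to 0.654). Adjusted over the list alone, the numbers that rose and fell were 23 and 4 for MAPK output, 15 and 3 for neural crest-like, 3 and 16 for the AXL-high list, 7 and 20 for the matrix list, 4 and 13 for TGF-beta, 1 and 7 for fibroblast, 1 and 7 for keratinocyte markers.

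In the list of p53 targets 18 of 25 fell and 3 rose (adjusted p = 1.01e-05, and 0.307 with an estimated correlation), with TP53INP1 4.502-fold and SESN2 2.201-fold lower. In the S phase list 10 of 39 rose and 0 fell (adjusted p = 0.0272, and 0.816 with an estimated correlation): E2F2 rose 2.802-fold, POLA1 2.13-fold and POLE 1.78-fold. The share that rose is near that over all genes. The S phase list lost its call without persister 1 (adjusted p = 0.0757) or persister 5 (0.0684), within a range of 4.73e-05 to 0.816, and with fry (0.138). In the interferon list 26 of 41 fell and 1 rose (adjusted p = 6.20e-04, and 0.744 with an estimated correlation): ISG15 fell 11.3-fold, IRF1 3.75-fold and IFITM2 2.07-fold. In the lysosome list 26 of 33 fell and 3 rose (adjusted p = 8.47e-06, and 0.654 with an estimated correlation): GABARAPL1 fell 2.93-fold, LAMP1 2.396-fold and ATP6V0D1 2.36-fold. The nuclear oxidative phosphorylation list had 26 of 37 lower and 1 higher (adjusted p = 6.90e-04, and 0.750 with an estimated correlation), including ATP5MC1 (2.25-fold), COX6A1 (1.86-fold) and NDUFB3 (1.78-fold). Of the mitochondrially encoded genes 11 of 13 fell and 0 rose (adjusted p = 0.00126, and 0.654 with an estimated correlation): MT-ND1 fell 3.92-fold, MT-ND2 2.74-fold and MT-CO2 2.72-fold, while mitochondrial genes took 6.81% ± 2.26 of counts in persister and 3.55% ± 0.226 in withdrawn libraries. In cholesterol synthesis 12 of 24 rose and 3 fell (adjusted p = 0.0498, and 0.654 with an estimated correlation): STARD4 rose 3.29-fold and FDFT1 1.68-fold. That call ended with the replicate block (adjusted p = 0.0759) and without persister 3 (0.0891), 4 (0.0508) or 5 (0.0519) or withdrawn 1 (0.0555), 3 (0.0727) or 4 (0.0519), within a range of 7.07e-04 to 0.654. With the block the pigmentation list (adjusted p = 0.0191, against 0.0633 without it) and the mitosis list (0.0434, against 0.0637) passed the test. Over all alternatives the adjusted p of these lists ranged from 0.00676 to 0.654 and from 1.61e-04 to 0.823. Adjusted over the list alone, the numbers that rose and fell were 3 and 18 for p53 targets, 3 and 0 for S phase, 1 and 26 for interferon, 3 and 26 for lysosome, 1 and 27 for oxidative phosphorylation, 0 and 12 for mitochondrially encoded genes, 12 and 3 for cholesterol synthesis. The lists that did not pass are given with the numbers higher and lower, and in brackets those adjusted over the list alone and the list's adjusted p. They were 6 and 9 of 21 for pigmentation (6 and 10, 0.0633), 1 and 0 of 35 for mitosis (0 and 0, 0.0637), 8 and 14 of 25 for antigen presentation (8 and 15, 0.283), 12 and 11 of 33 for the Mediator complex (12 and 11, 0.484), 4 and 1 of 40 for ribosomal proteins (1 and 0, 0.443), 8 and 14 of 30 for YAP and TEAD targets (9 and 15, 0.284). There were 11 and 14 of 36 for receptor tyrosine kinases (11 and 14, 0.484), 8 and 10 of 29 for NF-kB and inflammatory secretion (8 and 10, 0.620), 5 and 7 of 16 for the AP-1 family (5 and 7, 0.145), 8 and 8 of 24 for glycolysis (9 and 8, 0.0962), 8 and 12 of 30 for stress and unfolded protein response (8 and 12, 0.480), 11 and 8 of 24 for drug tolerance markers (11 and 9, 0.528). There were 4 and 3 of 9 for leukocyte markers (4 and 3, 0.484), 6 and 3 of 10 for endothelial markers (6 and 3, 0.329), 3 and 7 of 18 for heat shock (3 and 7, 0.230). The median and the test differed in sign for NF-kB, glycolysis, drug tolerance and leukocyte markers, and the median and the mean for antigen presentation. With fry 7 of these lists passed: pigmentation (adjusted p = 0.00939), AP-1 (0.00656), heat shock (0.0323) and drug tolerance (0.0383) were lower, and glycolysis (0.00199), leukocyte (0.00338) and endothelial markers (0.00267) higher. Pigmentation also passed with DESeq2 (0.0323), without persister 1 (0.0284) or 3 (0.0204) and without withdrawn 4 (0.0422). Mitosis passed with upper-quartile factors (0.0496), limma-voom (0.00698), without a low-count filter (0.00168) and without persister 2 (0.0272), 3 (0.0204) or 4 (0.0423). It also passed with voom and group quality weights (1.61e-04), a choice made after seeing the data. With the block and without 1 pair, AP-1 passed without pair 1 (0.0243) or 5 (0.0426), leukocyte markers without pair 3 (0.0224) and YAP and TEAD targets without pair 5 (0.0212).

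Among the other genes of interest, EGFR fell 3.81-fold and MITF rose 1.35-fold to 138 ± 24.2 CPM after withdrawal. MED12, CDK8, CDK19 and CCNC rose 1.83-fold, 1.53-fold, 1.45-fold and 1.48-fold, and BRAF 1.25-fold. BRAF lost its call without pair 3 under the replicate block (adjusted p = 0.0656), and MITF with voom and group quality weights (0.0740), a choice made after seeing the data. MAP2K1 rose 1.16-fold, a call that ended without withdrawn 1, 2 or 3 (adjusted p of up to 0.0592, and 0.00449 to 0.139 over all alternatives). AXL stood at 181 ± 36.3 CPM in withdrawn cells (adjusted p = 0.118), NGFR at 23.3 ± 5.795 (0.0922), CCND1 at 271 ± 28.5 (0.376) and MKI67 at 630.5 ± 53.7 (0.293). NGFR passed without persister 1 (0.0182) and with DESeq2 (0.0430), CCND1 without persister 2 (0.00279) and AXL without persister 5 (0.0139). In simulations of this comparison DESeq2 made 81 false calls of 223, where edgeR made 13 of 127. In the Mediator list 12 of 33 rose and 11 fell (adjusted p = 0.484). In all, 5794 genes were higher and 6634 lower in withdrawn than in persister cells, and with limma-voom 6192 and 6145. In 40.6% of tested genes the 5 withdrawn and 5 persister libraries did not overlap, where chance gives 0.794%.

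**Figure D2:**
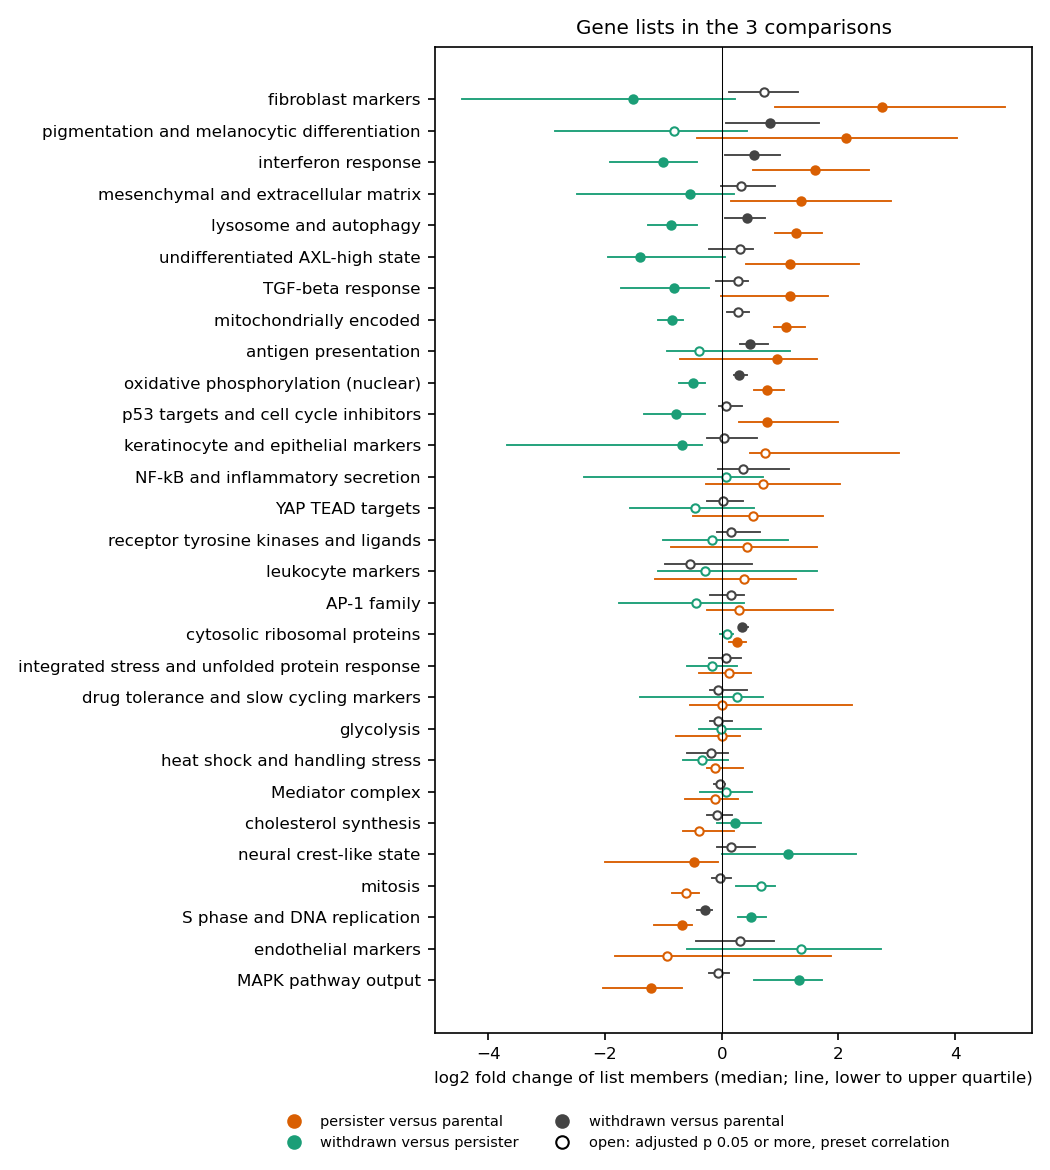
Median log2 fold change of the tested members of each of the 29 gene lists (points) with the lower and upper quartile (lines), in the 3 comparisons. Filled points passed the test with the preset correlation, none of which passed with an estimated one; the MAPK pathway list lies at -1.21 in persister against parental, 1.32 in withdrawn against persister and -0.06 in withdrawn against parental cells.

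How far the persister changes were undone was counted from the calls of the 3 comparisons. Of the 7391 genes called between persister and parental cells, 6375 (86.3%) were called in the opposite direction after withdrawal and were no longer called against parental cells. Not being called is not a return to the parental level, since that comparison recovered 5.97% of simulated 2-fold changes. These genes include MME, at 9.95 ± 8.96 CPM against 0.168 in parental cells, and POSTN, at 6.62 ± 5.97 against 0.0153. They also include TRPC4 (4.11 ± 4.39), ROS1, RARRES2 (0.131 ± 0.185) and CNTN6 (0.175 ± 0.1204), all at 0 counts in parental cells. A further 31 were partly reverted, 19 were retained and 9 were called in opposite directions against parental cells, while 957 could not be placed. The retained genes include EPB41L3, a cytoskeletal adaptor on chromosome 18 (5392381 to 5630700), which stood at 0.138 CPM in parental, 70.5 ± 22.3 in persister and 59.4 ± 12.8 in withdrawn cells. FBXL7 stood at 0.5201, 23.9 ± 12.9 and 37.2 ± 4.22 CPM, and the retinoic acid receptor gene RARB at 2.19, 12.8 ± 4.79 and 12.95 ± 1.12 CPM. P2RX7, an ATP-gated channel, stood at 3.29, 19.4 ± 6.36 and 19.4 ± 2.39 CPM, and the phosphatase gene PTPRM at 15.9, 77.9 ± 18.6 and 75 ± 10.1 CPM. Among the 4854 genes that differed at least 2-fold between persister and parental cells, withdrawal undid a median 78.7% of the log2 change (quartiles 55.9% and 97.2%). With different persister libraries on each side of that ratio, the median lay between 67.7% and 89.0%. Those splits kept the same genes and the single parental library, so this range does not cover error in that library. Such error enters both the choice of genes and the ratio. These class sizes depend on how the spread was estimated. With each comparison fitted on its own libraries, a choice made after seeing the data, 1271 genes were reverted, 862 partly reverted, 61 retained and 144 overshot. With voom and group quality weights, also chosen after seeing the data, 6276 were reverted and 1557 retained. Without persister 1, 2, 4 or 5, 37, 103, 40 and 155 genes were retained, and without withdrawn 1, 3, 4 or 5, between 3 and 4. The partly reverted were 90, 18, 55 and 132 without persister 2, 3, 4 or 5 and 10, 12, 9 and 8 without withdrawn 1, 3, 4 or 5. Those in opposite directions were 15, 29, 20 and 40 without persister 1, 2, 4 or 5 and between 2 and 4 without any 1 of the withdrawn libraries.

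**Figure D3:**
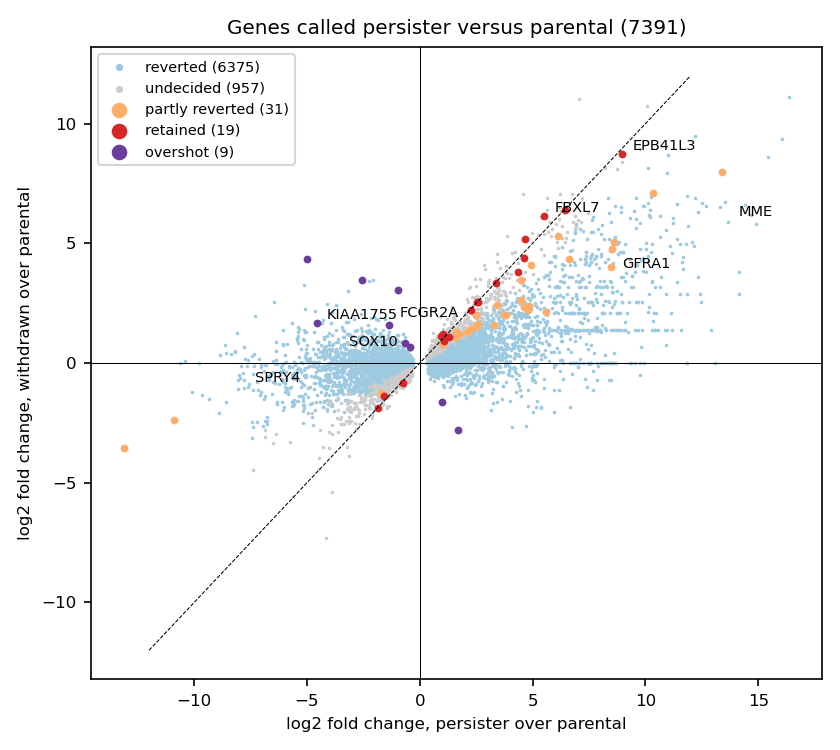
Log2 fold change of persister over parental (horizontal axis) and of withdrawn over parental cells (vertical axis) for the 7391 genes called between persister and parental cells, coloured by class. Points near the horizontal axis lie near the parental level and points near the dashed diagonal kept their change, such as EPB41L3 at 8.98 and 8.73.

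Withdrawn cells were compared with parental cells to see what remained different. TFRC, the transferrin receptor, stood at 509 CPM in parental and 471 ± 104 in persister cells and fell to 126 ± 13.8 CPM in withdrawn cells (log2 fold change -2.01 ± 0.23 (SE) against parental, adjusted p = 0.00330). TRA2A, a splicing regulator, fell 2.05-fold (log2 fold change -1.03 ± 0.11 (SE), adjusted p = 0.00237) and FAM13B 2.66-fold (adjusted p = 0.00290). EPB41L3 was 426-fold higher than in parental cells (log2 fold change 8.73 ± 0.80 (SE), adjusted p = 0.00230). SORL1, a sorting receptor, was 24.1-fold higher, NAV3 40.1-fold and GFRA1 26.8-fold. With limma-voom EPB41L3 (adjusted p = 0.0727) and GFRA1 (0.164) lost their calls.

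Other rises against parental cells were in CELF2 (58.2 ± 9.42 against 0.428 CPM), FBXL7 (71.2-fold), SEMA5A (19.2 ± 6.86 against 0.138 CPM) and PLXDC2, which had 2 parental counts and a ratio of 269 (95% counting interval 74.4 to 2224). Other falls were in PCDH9 (2.58-fold), CEMIP2 (2.35-fold), NBPF1 (2.24-fold), the amino acid transporter SLC38A1 (2.18-fold) and the microRNA processing factor DGCR8 (2.14-fold). Genes lower in persister and higher in withdrawn than in parental cells included KIAA1755 (3.15-fold higher after withdrawal), FCGR2A (3.01-fold), SUCLG2 (1.79-fold) and FBXO7 (1.61-fold). Leaving out 1 library ended many of these calls. CELF2 lost it without withdrawn 5 (adjusted p = 0.0511) and DGCR8 without withdrawn 1 or 5 (up to 0.0583). FBXL7 (up to 0.0701), PCDH9 (0.0707), SEMA5A (0.0782), SLC38A1 (0.0668) and KIAA1755 (0.0782) lost it without withdrawn 1, 3, 4 or 5, and PLXDC2 (0.0725) without withdrawn 1, 4 or 5. NBPF1 (0.0754) lost it without any 1 of the withdrawn libraries. CEMIP2 (0.0927), FCGR2A (0.0846), FBXO7 (0.0927) and SUCLG2 (0.100) lost it without persister 3 and without any 1 of the withdrawn libraries. Over all alternatives the adjusted p of these 13 genes ranged from 1.81e-23 to 0.258.

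DUSP6, SPRY4 and SOX10 were at 186 ± 9.28, 442 ± 60.7 and 814 ± 20.02 CPM, and none passed the test against parental cells (adjusted p = 0.771, 1.00 and 0.760). The same held for CDK8, CDK19, MED12, CCNC, MAP2K1, BRAF, MITF, NGFR, AXL, EGFR, CCND1 and MKI67 (adjusted p from 0.136 for MITF to 0.921 for CCNC). With the 6 withdrawn and parental libraries alone, SOX10 (adjusted p = 0.00185), CCND1 (0.0104), EGFR (0.0446), MKI67 (0.00445) and MAP2K1 (0.0455) passed it. MITF passed with DESeq2 (0.0344). Of the lists, 7 passed the test although none of their members did. With fry none of the 7 passed, with adjusted p of 0.0833 for ribosomal proteins, 0.0853 for pigmentation, 0.106 for antigen presentation, 0.185 for lysosome, 0.276 for oxidative phosphorylation, 0.421 for interferon and 0.659 for S phase. With the 6 withdrawn and parental libraries, each member named next passed it except DCT, with adjusted p from 5.94e-06 for CTSB to 0.0274 for BCL2A1. Leaving out 1 persister library also let some pass: CTSB without persister 1, 4 or 5 (adjusted p of up to 0.0499), CTSS without 4 or 5 (0.0455), IFITM2 without 2 or 5 (0.0268), PSMB8 (0.0439) and PSMB9 (0.0488) without 2 or 4, IFI35 without 4 (0.0385), and LAMP2 (0.0322) and IFITM3 (0.0478) without 5. DCT passed with DESeq2 (1.64e-04). The lysosome list had a median log2 fold change of 0.43 (adjusted p = 2.75e-05, and 0.654 with an estimated correlation), with CTSB at 164 and 354 ± 20.2 CPM, CTSS at 1.13 and 6.48 ± 1.08 and LAMP2 at 141 and 238 ± 19.8. Antigen presentation had a median of 0.48 (adjusted p = 6.09e-05, and 0.654 with an estimated correlation), with PSMB8 at 26.8 and 46.3 ± 2.05 CPM and PSMB9 at 6.99 and 14.3 ± 0.658. Ribosomal proteins had a median of 0.36 (adjusted p = 4.20e-08, and 0.654 with an estimated correlation), with RPL12 at 772 and 1190.5 ± 56.8 CPM, RPL13 at 717 and 1031 ± 39.6 and RPL37 at 595 and 844 ± 27.9. Nuclear oxidative phosphorylation had a median of 0.29 (adjusted p = 6.90e-04, and 0.750 with an estimated correlation), with UQCRC2 at 125 and 199 ± 7.76 CPM, UQCRB at 122 and 177 ± 4.98 and COX7C at 163 and 232 ± 9.696. The interferon list had a median of 0.56 (adjusted p = 0.0145, and 0.780 with an estimated correlation), with IFITM2 at 20.7 and 46.2 ± 2.55 CPM, IFITM3 at 178 and 284 ± 13.6 and IFI35 at 17.5 and 32.9 ± 1.93. Pigmentation had a median of 0.82 (adjusted p = 0.00359, and 0.654 with an estimated correlation), with DCT at 2.94 and 34.3 ± 20.8 CPM and BCL2A1 at 2.203 and 10.3 ± 3.41. S phase had a median of -0.29 (adjusted p = 0.0193, and 0.816 with an estimated correlation), with CCNE2 at 18.5 and 9.45 ± 0.497 CPM, E2F2 at 19.3 and 12.2 ± 0.709 and POLE at 105 and 70.7 ± 3.79. The other 22 lists did not pass the test, and their medians, with the adjusted p in brackets, were -0.06 for MAPK output (0.383), 0.16 for neural crest-like (0.238), 0.32 for AXL-high (0.849), 0.33 for matrix (0.0877), 0.28 for TGF-beta (0.216), 0.02 for YAP and TEAD (0.999), 0.16 for receptor tyrosine kinase (0.315), -0.03 for mitosis (0.748), 0.08 for p53 (0.234), 0.37 for NF-kB (0.111), 0.16 for AP-1 (0.754). They were -0.03 for Mediator (0.250), -0.07 for glycolysis (0.707), -0.07 for cholesterol (0.741), 0.08 for stress response (0.830), -0.06 for drug tolerance (0.534), 0.04 for keratinocyte (0.900), 0.72 for fibroblast (0.112), -0.54 for leukocyte (0.306), 0.32 for endothelial (0.868), 0.29 for mitochondrially encoded (0.383), -0.18 for heat shock (0.0637). 1 member each of the neural crest-like, drug tolerance and fibroblast lists rose. Adjusted over the list alone, 3 pigmentation, 1 interferon, 4 antigen presentation and 6 lysosome genes rose and 0 fell, and 0 rose and 0 fell in the ribosomal, oxidative phosphorylation and S phase lists. Among the lists that did not pass, the numbers that rose and fell were then 2 and 5 for heat shock, 3 and 1 for matrix, 2 and 1 for glycolysis, 3 and 0 for drug tolerance, 2 and 0 for p53, 0 and 2 for Mediator and 0 and 1 for endothelial markers. They were 1 and 0 each for neural crest-like, TGF-beta and fibroblast, and 0 and 0 for the others. Of the lists that did not pass, heat shock did, lower, with upper-quartile factors (0.0437), with the 6 libraries (0.00919), without persister 2 (0.0445) or 4 (0.0466) and without withdrawn 2 (0.0457). The matrix list did, higher, with the 6 libraries (0.0183) and without withdrawn 2 (0.0404), and the p53 list without a low-count filter (0.0499). The median and the test differed in sign for drug tolerance and keratinocyte markers. With genes at 0 on a side set to their bound, the medians were 0.65 for pigmentation, 0.54 for interferon, -0.11 for drug tolerance and -0.08 for keratinocyte markers.

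In all, 74 genes were higher and 28 lower in withdrawn than in parental cells, and 3609 genes had an unadjusted p under 0.05. With upper-quartile scaling the split was 57 to 38, and with limma-voom 57 to 52. The count rests on the spread shared with the persister libraries, whose median SD of log2 CPM was 0.270 against 0.0859 in the withdrawn libraries: with the 6 withdrawn and parental libraries alone, 3483 genes were higher and 3110 lower. Without persister 1, 2, 4 or 5 the numbers higher were 123, 252, 130 and 374 and those lower 46, 109, 48 and 184, and without persister 3 17 were lower. Without withdrawn 1, 3, 4 or 5 they were 22, 23, 20 and 19 higher and 5, 6, 7 and 4 lower, and without withdrawn 2 12 were lower. In the shared fit a simulated 2-fold change was recovered for 5.97% of genes in this comparison, and for 76.1% with those 6 libraries alone, with 0 false calls of 56 and 19 of 176. The simulated parental library had the spread of the withdrawn libraries, so these false calls do not cover a parental library that varies more. Of the 102 genes, 52 were also called in the same direction against persister cells, and 27 of these, TFRC and TRA2A among them, were not called between persister and parental cells.

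The libraries differed more within the persister group than within the withdrawn group. Pearson correlations of log2 CPM, across genes, which are not independent replicates, had a median of 0.972 between persister libraries and 0.989 between withdrawn libraries. They were 0.976 between withdrawn and parental and 0.912 between persister and parental libraries. The SD was larger among persister libraries for 94.1% of 13350 genes. The mean log2 CPM of the mitosis list was 6.97 in parental cells. It was 5.17 in persister 1, 7.05, 6.83 and 6.78 in persister 2, 3 and 4, and 3.81 in persister 5, and it lay between 6.92 and 7.03 in the withdrawn libraries. MKI67 averaged 384 ± 275 CPM in persister and 630.5 ± 53.7 CPM in withdrawn cells, and 0 of 35 mitosis genes rose and 0 fell against parental cells (adjusted p = 0.111). When each library was set against the other 4 of its group, edgeR called at most 1 gene for a persister and 15 for a withdrawn library.

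The comparisons share libraries, which by itself correlates their fold changes. Fold changes of persister and of withdrawn over parental cells had a correlation of 0.472 across genes and a covariance of 0.564. In 20 simulations with no change in any gene these were 0.732 and 0.177, so the covariance exceeded the simulated one by 0.387. Of the genes called, 59 were higher and 7 lower in both, where independent lists would share 11.9 and 4.22, numbers that ignore the shared parental library. As only 1 parental library exists and enters both fold changes, part or all of the excess may come from that library. The simulated parental library had the spread of the withdrawn libraries, so the simulations do not cover one that varies more. The 2 fold changes had the same sign for 68.9% of genes, against 71.7% in the simulations. Fold changes of persister over parental and of withdrawn over persister cells had a correlation of -0.866 and a covariance of -1.82, against -0.511 and -0.0982 in simulations. With different persister libraries on each side the correlation lay between -0.815 and -0.744 and the covariance between -1.79 and -1.65. Of the genes called, 3285 were higher in persister cells and lower after withdrawal and 3130 the reverse, where independent lists would share 1069 and 873.5, numbers that ignore the shared persister libraries.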

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

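The tests of detection at equal counts and of the lone parental library were chosen only after the results they bear on were seen; the split of the samples and the poly(A) test were not. In 332 groups of 5 values, 24 held a library far from the other 4, where chance flags about 1 in 20 groups: 1 of 18 quality measures, 9 of 58 list means and 14 of 256 named genes.

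Among the persister libraries, the mean log2 CPM of the MAPK list was 5.27 in persister 2 (others 4.62 to 4.79), that of the neural crest-like list 4.60 in persister 4 (3.93 to 3.99) and that of the TGF-beta list 5.27 in persister 1 (5.72 to 5.85). The p53 list stood at 5.54 in persister 2 (5.29 to 5.34), glycolysis at 7.32 in persister 1 (7.14 to 7.17) and leukocyte markers at -1.44 in persister 3 (-1.95 to -1.82). DUSP6 was at 33.1 CPM in persister 2 (21.2 to 23.9), RXRG at 4.71 in persister 4 (1.52 to 2.01), STARD4 at 15.8 in persister 5 (12.4 to 13.2) and EPB41L3 at 33.7 in persister 2 (70.5 to 92.0). BTG2 was at 61.1 CPM in persister 5 (36.5 to 40.2) and IFI35 at 21.9 in persister 4 (38.4 to 48.1).

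Among the withdrawn libraries, mitochondrial genes took 3.15% of counts in withdrawn 3 (3.61 to 3.70). The mean log2 CPM of the AXL-high list was 5.01 in withdrawn 3 (4.50 to 4.64), of the interferon list 3.43 in withdrawn 3 (3.20 to 3.26) and of the Mediator list 4.90 in withdrawn 2 (4.85 in each of the others). NDUFB3 was at 31.9 CPM in withdrawn 5 (34.5 to 35.3), COL5A1 at 5.70 in withdrawn 4 (12.3 to 14.4), CDK8 at 28.4 in withdrawn 3 (32.0 to 32.8) and MYOCD at 0.356 in withdrawn 4 (0 to 0.0148). RPS20 was at 908 CPM in withdrawn 2 (796 to 816), NUAK1 at 8.14 in withdrawn 2 (10.7 to 11.4), RARRES2 at 0.460 in withdrawn 3 (0.0285 to 0.0701) and ANO1 at 13.4 in withdrawn 4 (20.5 to 23.0). Against parental cells, 9 genes were called in opposite directions in persister and in withdrawn cells.

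Between withdrawn and persister cells the 10 libraries gave 11057 calls. Of 100 drawn splits, the real split among them, 1 gave as many and the highest other gave 0. This argues against chance only among splits that ignore the pairs. Every other split mixes persister with withdrawn libraries, which widens the spread within its groups. Of the splits, 14 part all same-numbered pairs, the real split among them, and the highest of the others among these also gave 0. These 14 are too few to reach a share under 0.05, and no split tests whether the cultures are independent.

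Mitochondrially encoded RNA was higher in persister libraries, with a median log2 fold change of 0.85 over withdrawn libraries and a lower quartile of 0.66. Weaker poly(A) selection would also raise RNA without a poly(A) tail. The 216 small nuclear, small nucleolar and related genes had a median of -0.39, which argues against weaker selection as the whole cause. The 95% interval of that median, -0.49 to -0.25, comes from resampling genes and does not cover the spread between cultures. The ratio of mitochondrial mRNA to rRNA goes the other way. It was 6.55 in persister and 8.55 in withdrawn libraries (exact two-sided permutation test that ignores the pairs, p = 0.00794), with mitochondrial rRNA at 0.921% and 0.375% of counts. With mitochondrial genes left out, 4 of 5 persister libraries detected at least as many genes as the lowest withdrawn library at 53963071 counts each. The persister libraries thus did not all detect fewer genes. Detection of the other genes cannot decide what raises the mitochondrial share. Nuclear genes of oxidative phosphorylation were higher as well. The drug, by which the design separates these groups, stays open as an untested explanation.

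Of the 102 genes called between withdrawn and parental cells, 25 (24.5%, 95% exact interval 16.5% to 34.0%) had the parental library inside the range of the other 10 libraries. It lay between the groups for 15 of them and among the persister libraries for 10. A parental library that stands apart from all others was predicted to lie outside that range. A parental library that deviates from the withdrawn towards the persister libraries would lie inside it. This count therefore cannot decide whether the parental library is the source of these calls. Of the other 77, 24.7% (95% exact interval 15.6% to 35.8%) were not called between withdrawn and persister cells. For all 102 genes a deviating parental library cannot be told apart from a lasting effect of the treatment, because no second parental library was analysed here. Time in culture cannot be told apart from either of these, since the labels give none for the parental cells.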

How the results depend on the processing

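The fits of each comparison on its own libraries, voom with group quality weights and leaving out mitochondrially encoded genes were tests chosen only after the results were seen. Directions were compared for the named genes and the gene lists only. No call of these changed direction under any alternative run. Named genes not called in either fit changed sign in 7 instances, counted over all comparisons and alternatives, so 1 gene can count more than once. Where no cause is named below, the cause was not tested. With upper-quartile factors 5 genes were overshot. With at least 10 counts in 5 libraries, 49 genes were lower in withdrawn than in parental cells, 37 retained and 15 overshot. Under that filter 4 list calls were lost and 1 was gained over the 3 comparisons. With DESeq2, 775 were higher and 409 lower in withdrawn than in parental cells, 292 partly reverted, 316 retained and 89 overshot. With limma-voom 52 were lower in withdrawn than in parental cells and 14 overshot. An absolute log2 fold change of at least 1, which by construction removes calls, left 2864 higher and 3606 lower in withdrawn than in persister cells, 2217 lower in persister than in parental cells, 3431 reverted, 18 partly reverted, 32 retained and 5 overshot. With the 6 persister and parental libraries, 1354 were higher and 1215 lower. With the 6 withdrawn and parental libraries, 3483 were higher and 3110 lower. On their own libraries 1271 were reverted, 862 partly reverted, 61 retained and 144 overshot. With quality weights, 3033 were higher and 2869 lower in withdrawn than in parental cells, 1474 partly reverted, 1557 retained and 541 overshot. With an estimated correlation 0 lists passed in each comparison, and with fry 0 for withdrawn against parental cells, where 20 passed for withdrawn against persister and 15 for persister against parental cells. The replicate block, which uses the pairing, gave 5211 genes higher and 5419 lower in withdrawn than in persister cells, and 4408 lower without pair 3. The block fit leaves out the parental library. Of its 10630 calls, 10324 were also made in the fit of all 11 libraries without the block. Against that fit, 1 of the 29 lists lost its call, 2 gained a call and none of the 70 named genes changed sides. Leaving out each library in turn gave 19 to 374 genes higher and 4 to 184 lower in withdrawn than in parental cells, 8 to 132 partly reverted, 3 to 155 retained, 2 to 40 overshot and 5592 to 7455 reverted. It gave 5058 to 6091 higher and 5915 to 6851 lower in withdrawn than in persister cells, and 3326 to 4614 higher and 3148 to 4235 lower in persister than in parental cells. Depth limits the values of genes near 0 counts, such as POSTN and COL1A2 in parental cells, while the single parental library limits both comparisons with it.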

Other observations

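All genes named here were picked from 3 lists after their values were seen, and their tests are those of the comparisons. In the pigmentation list, other genes were also higher in persister than in parental cells. DCT, an enzyme of melanin synthesis, stood at 2.94 CPM in parental, 424 ± 216 in persister and 34.3 ± 20.8 in withdrawn cells (log2 fold change of persister over parental 7.17, adjusted p = 0.00175). GPNMB, a melanosome glycoprotein, stood at 205, 1485 ± 591 and 469 ± 89.1 CPM (2.85, adjusted p = 0.00236), and PPARGC1A, a regulator of mitochondrial genes, at 0.275, 35.1 ± 18.5 and 1.74 ± 0.792 CPM (6.98, adjusted p = 0.00114).

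The antigen presentation list moved in both directions between persister and parental cells. The class I genes B2M and TAP1 rose (log2 fold change 1.63 and 1.12, adjusted p = 9.79e-04 and 0.00220). The class II regulator CIITA and the class II chaperone CD74 fell (-2.75 and -1.36, adjusted p = 5.13e-04 and 0.0223), and after withdrawal they rose (2.77 and 1.94, adjusted p = 1.44e-05 and 9.24e-05). In the Mediator list MED14, MED12L and MED13 fell in persister cells (-1.39, -2.26 and -0.89), while MED11, MED29 and MED19 rose (0.74, 0.62 and 0.56).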
